A study of Zea mays with 26 samples.

How the data were processed

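The series held 26 libraries: 12 of bulk RNA-seq (6 ages), 6 of ATAC-seq, 3 of single-cell RNA-seq and 5 of CUT&Tag, by their labels. The ATAC-seq and CUT&Tag libraries, 11 in all, were not analysed here. Samples were placed in groups by the age in their titles. All tissue came from the genotype B73, per the labels.

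For bulk RNA-seq the authors deposited raw counts per gene and library, whole numbers with no normalization, for 44481 identifiers. The single-cell values the authors deposited are raw counts per gene and cell in 1 matrix of 17563 cells and 26993 genes, whose column names give the library. SAMs for bulk RNA were frozen at once after collection, and single cells were released enzymatically as protoplasts, per the labels' protocols. Trimmomatic 0.33, HISAT2, SAMtools 1.9, Bowtie2, STAR, Seurat 4.3.0 and the genome build B73 RefGen_v4 are named, with no role, per the submitters' processing notes. The counting tool and the use of strand are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. No cell in the deposited matrix had under 2600 counts.

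Gene names came from the bulk table itself or from the reference table of Zm-B73-REFERENCE-NAM-5.0, which matched 155 of the 44481 identifiers. Of these 153 were microRNA genes, and 0 of the 44146 identifiers that start with Zm00001d matched. The 31 gene lists and the cell type markers fixed before the data were examined had 0 members among the matched identifiers. The gene list tests, the flowering genes set out by name and the naming of clusters by markers were therefore not run. No coordinates are given, because the table is of another build.

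Genes were kept with edgeR's filterByExpr (22001 genes). The main test was edgeR 4.0.16 in R 4.3.3: TMM factors, a quasi-likelihood fit with robust estimates over the 12 libraries with age as a factor, an F test over the 6 ages for the time course and 7 contrasts between ages. Calls were made at a Benjamini-Hochberg false discovery rate of 0.05 over all genes tested. SEs of log2 changes were derived from the fitted change and its F statistic. The rule for named genes, fixed before the data were examined, took up to 8 genes per direction and contrast with a call, libraries of the ages not overlapping, a mean of at least 5 CPM at the higher age and a name. It named 8 microRNA genes. The other named microRNA genes (MIR528a, MIR166c, MIR166m, MIR396a, MIR167c and MIR394a among those called between ages, with MIR166k and MIR319c in the time course), the calls or values of named genes in comparisons outside the rule, and MIR172e, were singled out after their values were seen. At most 2 identifiers per direction and contrast are named for genes without a name.

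Counts were simulated for 22 to 26DAS (22001 genes, 200 changed). The bulk test recovered 45 of 100 genes changed by a fold of 2 and 90 of 100 changed by a fold of 4, and called 9 unchanged genes. The changed genes were drawn from those above a minimum expected count, with the same spread of a gene at all ages. Recovery of genes with few counts, such as MIR166m, was therefore not measured. The libraries of each age differed by more than counting noise (a chi-square per degree of freedom from 2.49 to 82.3), so none was treated as a repeat of another. Counting intervals for ratios and shares are at the 95% level, and a floor stands for 3 counts; both cover counting error only.

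Cells were scaled to 10000 counts and log-transformed in scanpy 1.11.5. The 2000 most variable genes, chosen with the library as batch, gave 30 principal components, a graph of 15 neighbours and Leiden clusters at resolution 1 (igraph 0.11.9). No doublet caller was run, and no cells were removed. The planned filter of at least 1000 counts per cell removes 0 cells and was not used. Distances and graph weights were rounded to 3 decimals so that the clustering does not depend on the processor. Earlier versions of the clustering, with other rounding, were seen before this one was fixed, and they divided the larger clusters differently. The rule for reporting shares (a ratio of at least 2 with intervals apart), the overlap of 0.8 and the minimum of 100 cells per library in the comparisons within clusters were also set after values were seen. Counts were summed per library, and changes were ratios of CPM with 0.5 added to each count, for genes with at least 20 counts over the 3 libraries. On simulated counts for 22 to 26DAS, 99.5% of 200 genes changed by a fold of 2 moved the right way, against 50.2% of unchanged genes. That simulation held counting error only, with no spread between libraries.

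Alternatives fixed beforehand were RLE size factors, no count filter, DESeq2 1.42.0, the replicate number as a block, the 2 ages alone, each library left out in turn, resolutions of 0.5 and 1.5, 1000 variable genes, a minimum of 100 counts, TMM over the summed single-cell libraries and DESeq2 calls. Added after the data were seen were fits with 14DAS left out, agreement of calls made without each library, clustering without the bulk genes called with age (1207 variable genes left), 5 other Leiden seeds, graph weights to 2 decimals and a minimum of 50 cells.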

Results

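Maize plants of the inbred line B73 were sampled across the floral transition, when the shoot apical meristem (SAM), the stem cell tissue at the tip of the shoot, turns from making leaves to making an inflorescence. Bulk polyA RNA sequencing covered SAMs at 14, 16, 18, 22, 26 and 28DAS (the age unit of the labels), with 2 libraries per age and 12 in all. Single-cell RNA sequencing of protoplasts from dissected apices with their youngest leaf primordia covered 14, 22 and 26DAS, with 1 library per age. The bulk libraries held from 9153234 counts (14DAS replicate 1) to 20031049 (28DAS replicate 1), and the other 14DAS library held 15370269. The single-cell libraries held 5746, 5829 and 5988 cells, with medians of 6342.5, 8538 and 7818 counts per cell. Nothing in the labels says that the bulk replicates came from separate plants, so the p-values measure only the spread between these libraries, which may be technical.

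MicroRNA genes carry their names in the count table, and the other genes carry identifiers that the reference table used here does not name. The values below are for the polyadenylated precursor transcripts of microRNA genes, not for the mature microRNAs. Levels are CPM values, which are counts scaled to library size with TMM factors, given as mean ± SD with n = 2 libraries per age. Near-identical gene copies, such as MIR398a with MIR398b and the MIR166 members, can share reads, so the split between copies is uncertain.

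Over the whole time course, 16 of the 29 microRNA genes tested changed with age, as did 6344 of the 22001 genes tested (28.8%; edgeR quasi-likelihood test, false discovery rate 0.05). MIR398a, MIR398b, MIR408b and MIR528a, whose families are known for targeting transcripts of copper proteins, had their highest mean at 18DAS; they are named together after their values were seen, and no test was made of them as a group. Of these, MIR398a and MIR528a passed the test neither from 16 to 18DAS (edgeR adjusted p = 0.427 and 0.386) nor from 18 to 22DAS (edgeR adjusted p = 0.317 and 0.579). MIR397, another such family, had 4 counts in all and was not tested. MIR159f, MIR319c and MIR394a were highest at 16DAS, and MIR396a and MIR167c at 14DAS. MIR159a, MIR160b, MIR160d, MIR166a, MIR166c and MIR166m were highest at 28DAS, and MIR166k at 26DAS. Among all 6344 genes, 2321 were highest at 28DAS, 1546 at 14DAS and 1200 at 16DAS, against 356 at 18DAS and 257 at 22DAS. The order of 14 and 16DAS turned without 14DAS replicate 1, and the shares of 18 and 22DAS were larger. Of the 16 microRNA calls, 9 were kept under every alternative. Lost were the calls of MIR160d without 28DAS replicate 2, MIR166a, MIR166c and MIR166m without either 28DAS library, MIR166k and MIR166m without 16DAS replicate 1, MIR167c without 28DAS replicate 1, and MIR396a without each library in turn of 16, 18, 22 or 28DAS and without 26DAS replicate 1. The total over all genes was 3053 genes without 28DAS replicate 2, 3109 without 28DAS replicate 1, 3950 without 16DAS replicate 2 and 4084 without 16DAS replicate 1. It was 11690 without 14DAS replicate 1, 17160 without 14DAS replicate 2 and 11892 with both 14DAS libraries left out.

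**Figure D1:**
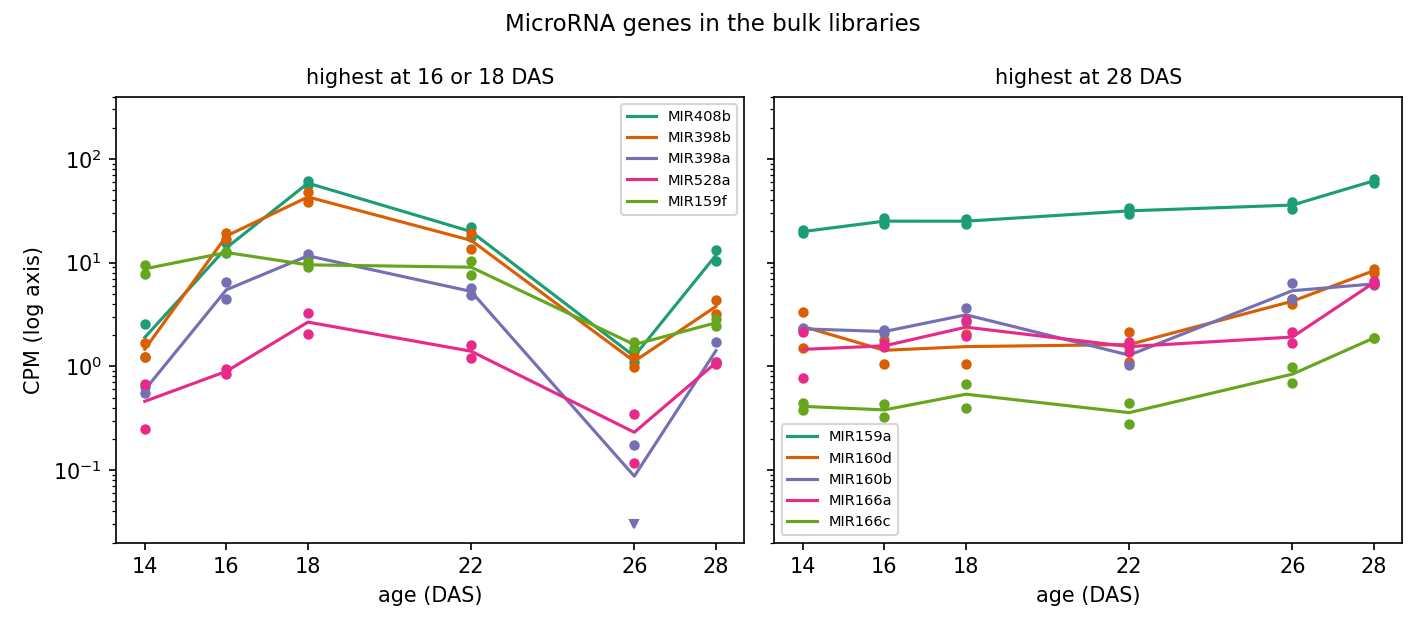
Levels of 10 microRNA genes in the bulk libraries by age (DAS), in CPM on a log axis, with points for the 2 libraries per age and lines through the means. A triangle marks a library with 0 counts. MIR408b and MIR398b had their highest means at 18DAS, 58.5 and 43.0 CPM, and lay at 1.25 and 1.12 CPM at 26DAS, and MIR159a reached 61.6 CPM at 28DAS.

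The first step, from 14 to 16DAS, asks what changes at the start of the series. MIR398b rose from 1.46 ± 0.332 to 18.1 ± 1.69 CPM, a log2 change of 3.58 (SE 0.285, edgeR adjusted p = 0.00115). MIR408b rose from 1.9 ± 0.954 to 13.9 ± 2.18 CPM, a log2 change of 2.78 (SE 0.294, edgeR adjusted p = 0.00518). MIR398a rose from 0.593 ± 0.050 to 5.48 ± 1.37 CPM (log2 change 3.17, SE 0.437, edgeR adjusted p = 0.0182). These were the 3 called among the 29 microRNA genes, and 4 were called when adjusted over the list alone. Among the identifiers, Zm00001d017147 rose from 0.293 ± 0.0588 to 7.65 ± 0.364 CPM (log2 change 4.72, SE 0.335). In all, 75 genes rose and 91 fell, 166 together by edgeR. The fit of the 2 ages alone called 0 genes (1217 at an unadjusted p under 0.05, these 4 genes not called), DESeq2 called 1217 genes (517 higher and 700 lower), and 304 were called with no count filter (108 and 196). Every fit without a library moved the total by over 1.5 times, from 16 without 16DAS replicate 1 (15 higher and 1 lower) to 11709 without 14DAS replicate 2 (6116 and 5593). The MIR398a call was lost without either library of 16DAS or of 22DAS, and the MIR408b call without 16DAS replicate 1; the MIR408b log2 change was 3.49 without 14DAS replicate 2.

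From 16 to 18DAS, MIR408b rose again, from 13.9 ± 2.18 to 58.5 ± 3.64 CPM, a log2 change of 2.07 (SE 0.240, edgeR adjusted p = 0.0418). MIR398b stood at 43.0 ± 6.63 CPM at 18DAS, a log2 change of 1.25 (SE 0.222) that did not pass the test (edgeR adjusted p = 0.138). The identifier Zm00001d033987 rose from 0.964 ± 0.0705 to 27.2 ± 1.75 CPM (log2 change 4.81, SE 0.318, edgeR adjusted p = 0.00213). Of 29 microRNA genes, 1 was called, and 2 when adjusted over the list alone. That call was lost with the replicate number as a block. In all, 8 genes rose and 0 fell by edgeR, with 1494 genes of either direction at an unadjusted p under 0.05. DESeq2 called 203 genes (161 higher and 42 lower), the fit of the 2 ages alone 35 (32 and 3), the fit with no count filter 50 (49 and 1) and the fit with 14DAS left out 261 (195 and 66). The MIR408b call was lost in 10 of the 12 fits without a library, all but those without a 14DAS library, with log2 changes from 1.92 to 2.24. The Zm00001d033987 call was lost without either 16DAS library. The total was 263 without 14DAS replicate 1, 256 without 14DAS replicate 2 and 0 to 4 without any other library; it was 0 without either 16DAS library, with 794 and 864 genes at an unadjusted p under 0.05.

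From 18 to 22DAS these transcripts came down. MIR408b fell to 19.9 ± 3.15 CPM (log2 change -1.55, SE 0.234, edgeR adjusted p = 0.0345), and MIR398b fell to 16.4 ± 4.04 CPM (log2 change -1.39, SE 0.223, edgeR adjusted p = 0.0429). Zm00001d033987 fell from 893 counts over both 18DAS libraries to 2 over both 22DAS libraries, a ratio of 446 (95% counting interval 123 to 3690). Of 29 microRNA genes, 2 were called, and 6 when adjusted over the list alone. Both calls were lost with the replicate number as a block. In all, 12 genes rose and 63 fell by edgeR. DESeq2 called 287 genes (106 higher and 181 lower), the fit of the 2 ages alone 136 (39 and 97) and the fit with 14DAS left out 553 (250 and 303). Each fit without a library moved the total of 75 by over 1.5 times, from 9 without 22DAS replicate 1 (0 higher and 9 lower) to 554 without 14DAS replicate 2 (251 and 303). Both microRNA calls were lost in 10 of the 12 fits without a library, all but those without a 14DAS library.

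The step from 22 to 26DAS held more calls than any other step between neighbouring ages in the fit of all 12 libraries. That order was kept without 14DAS replicate 1 and lost to the step from 14 to 16DAS without 14DAS replicate 2. Each of those fits leaves a lone 14DAS library, which is assumed to vary like those of other ages. MIR408b fell from 19.9 ± 3.15 to 1.25 ± 0.204 CPM, a log2 change of -3.97 (SE 0.301, edgeR adjusted p = 0.000321), and MIR398b fell from 16.4 ± 4.04 to 1.12 ± 0.182 CPM, a log2 change of -3.87 (SE 0.287, edgeR adjusted p = 0.000292). MIR398a went from 171 counts to 3, a ratio of 55.2 (95% counting interval 18.6 to 270). Its 3 counts were in 26DAS replicate 1: the ratio was 30.0 without replicate 2, and without replicate 1 the gene was at least 25.4-fold lower against a floor of 3 counts over the group. MIR159f, of a family known for targeting GAMYB transcription factors, fell from 9.04 ± 2.01 to 1.62 ± 0.155 CPM (log2 change -2.47, SE 0.228, edgeR adjusted p = 0.000699). MIR528a fell from 1.40 ± 0.273 to 0.231 ± 0.163 CPM (log2 change -2.60, SE 0.568, edgeR adjusted p = 0.0295; -1.97 without 26DAS replicate 1 and -3.49 without replicate 2). MIR160b, of a family known for targeting auxin response factors, rose from 1.28 ± 0.341 to 5.36 ± 1.33 CPM (log2 change 2.07, SE 0.287, edgeR adjusted p = 0.00449). These were the 6 of 29 microRNA genes called (5 lower and 1 higher), and 11 were called when adjusted over the list alone.

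Across all genes, 716 rose and 692 fell from 22 to 26DAS, 1408 together (6.40% of those tested; edgeR). Zm00001d035232 went from 244 counts to 3, a ratio of 78.7 (95% counting interval 26.6 to 384). The ratio was 35.9 without 26DAS replicate 1, and without replicate 2, which held the 3 counts, it was at least 42.3. MIR398a, MIR398b, MIR408b and MIR159f kept their calls under every alternative. The MIR160b call was lost without 22DAS replicate 1, and the MIR528a call in 7 of the 12 fits without a library (either library of 16, 22 or 28DAS, or 26DAS replicate 1). DESeq2 called 2218 genes (1190 higher and 1028 lower), the fit of the 2 ages alone 3391 (1654 and 1737) and the fit with 14DAS left out 4283 (2151 and 2132). The total was 239 without 22DAS replicate 1 (97 higher and 142 lower), 289 without 22DAS replicate 2 (126 and 163), 317 without 26DAS replicate 1 (175 and 142), 870 and 873 without a 16DAS library, 848 and 847 without a 28DAS library, and 4283 and 4294 without a 14DAS library.

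**Figure D2:**
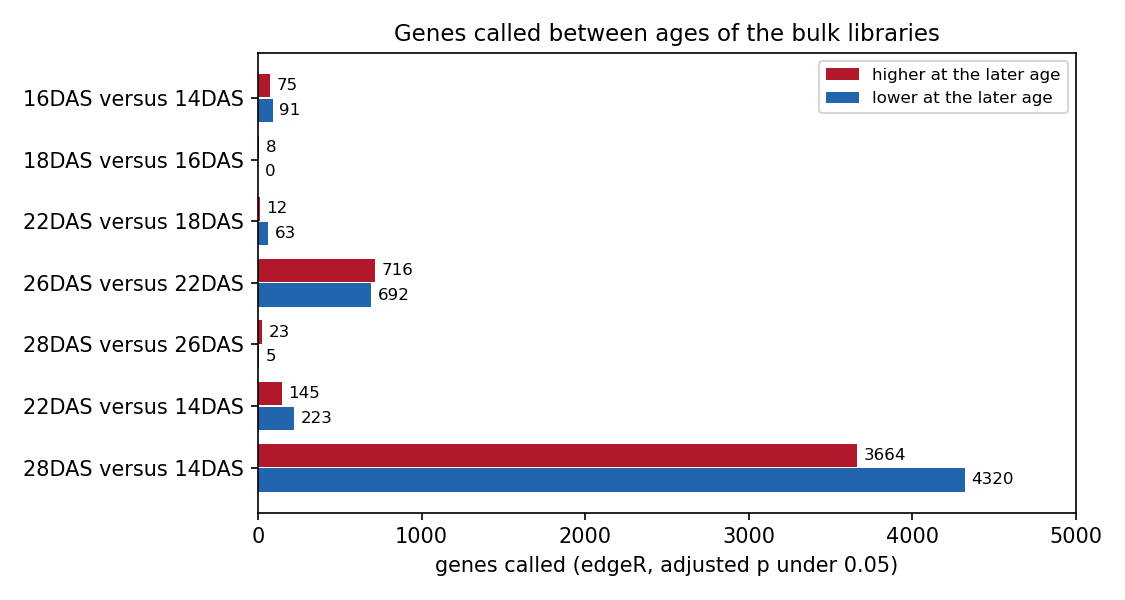
Number of genes called by edgeR in each comparison of ages, with bars to the right for genes higher (red) and lower (blue) at the later age. The step from 22 to 26DAS had 716 higher and 692 lower genes, and the whole span from 14 to 28DAS had 3664 and 4320.

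From 26 to 28DAS, MIR408b rose from 1.25 ± 0.204 to 11.8 ± 2.04 CPM, a log2 change of 3.22 (SE 0.302, edgeR adjusted p = 0.0267). MIR398b went from 1.12 ± 0.182 to 3.78 ± 0.866 CPM, which did not pass the test (log2 change 1.76, SE 0.303, edgeR adjusted p = 0.0639). Of 29 microRNA genes, 1 was called, and 7 when adjusted over the list alone. In all, 23 genes rose and 5 fell by edgeR, with 2689 at an unadjusted p under 0.05. DESeq2 called 590 genes (365 higher and 225 lower), the fit of the 2 ages alone 965 (479 and 486), the fit with no count filter 171 (124 and 47) and the fit with 14DAS left out 1233 (707 and 526). The total of 28 was 1228 without 14DAS replicate 1, 1213 without 14DAS replicate 2, 273 without 26DAS replicate 1 (169 higher and 104 lower), 1 without 28DAS replicate 1 and 0 without each other library, where 1233 to 2445 genes had an unadjusted p under 0.05. The MIR408b call was lost in 9 of these 12 fits, all but those without a 14DAS library or 26DAS replicate 1.

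From 14 to 22DAS, the span shared with the first single-cell libraries, MIR398b rose by a log2 change of 3.44 (SE 0.285, edgeR adjusted p = 0.000906) and MIR408b by 3.30 (SE 0.292, edgeR adjusted p = 0.00128). MIR398a rose from 0.593 ± 0.050 to 5.28 ± 0.565 CPM (log2 change 3.12, SE 0.436, edgeR adjusted p = 0.0112). Of 29 microRNA genes, 3 were called, and 5 when adjusted over the list alone. Zm00001d034045 rose from 1.01 ± 0.169 to 37.2 ± 2.17 CPM (log2 change 5.15, SE 0.155). In all, 145 genes rose and 223 fell by edgeR, and DESeq2 called 1645 (735 higher and 910 lower). The fit of the 2 ages alone called 0, these 4 genes included among those lost, with 1453 at an unadjusted p under 0.05. The total of 368 was 823 without 14DAS replicate 1 (417 higher and 406 lower), 11093 without 14DAS replicate 2 (5686 and 5407), 33 without 22DAS replicate 2 (20 and 13), 40 without 22DAS replicate 1 (26 and 14) and 164 to 201 without a library of 16, 18 or 28DAS. The MIR398a call was lost without either 22DAS library, and the MIR408b log2 change was 4.01 without 14DAS replicate 2.

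Over the whole span, from 14 to 28DAS, 8 of 29 microRNA genes rose and 4 fell, and 13 were called when adjusted over the list alone. MIR159a rose from 19.9 ± 0.763 to 61.6 ± 4.18 CPM (log2 change 1.63, SE 0.141, edgeR adjusted p = 0.000121), while MIR159f of the same family fell from 8.72 ± 1.23 to 2.63 ± 0.291 CPM (log2 change -1.72, SE 0.215, edgeR adjusted p = 0.000648). The family of MIR166, known for targeting class III HD-ZIP transcription factors, had 3 of its 4 tested members higher. These were MIR166a (log2 change 2.05, SE 0.383), MIR166c (2.19, SE 0.416) and MIR166m (2.23, SE 0.670). The sizes rest on few counts at 14DAS: 7 and 34 in replicates 1 and 2 for MIR166a, 4 and 6 for MIR166c, and 1 and 4 for MIR166m. MIR160b rose from 2.30 ± 0.0564 to 6.24 ± 0.175 CPM (log2 change 1.44, SE 0.275, edgeR adjusted p = 0.00456) and MIR160d from 2.43 ± 1.30 to 8.38 ± 0.494 CPM (log2 change 1.85, SE 0.449, edgeR adjusted p = 0.0133). MIR408b and MIR398b were also higher, by log2 changes of 2.54 (SE 0.293) and 1.33 (SE 0.302). Without 14DAS replicate 2 the log2 changes were 3.03 for MIR166a, 3.01 for MIR166m and 3.26 for MIR408b, and without 14DAS replicate 1 that of MIR160d was 2.47.

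The microRNA genes that fell over the same span were MIR159f, MIR394a, MIR396a and MIR167c. MIR394a, of a family known for targeting an F-box gene, fell from 2.05 ± 0.412 to 0.235 ± 0.0963 CPM (log2 change -3.05, SE 0.456, edgeR adjusted p = 0.00154). MIR396a, of a family known for targeting growth-regulating factors, fell from 3.96 ± 2.76 to 0.672 ± 0.308 CPM (log2 change -2.51, SE 0.687, edgeR adjusted p = 0.0210). MIR167c, of a family known for targeting auxin response factors, fell from 3.04 ± 0.120 to 0.718 ± 0.0862 CPM (log2 change -2.07, SE 0.402, edgeR adjusted p = 0.00504). The MIR396a log2 change was -1.58 without 14DAS replicate 1 and -3.13 without replicate 2. Lost calls were those of MIR160d and MIR166m without either 28DAS library, MIR166m also without 14DAS replicate 1, MIR396a without either 28DAS library or 14DAS replicate 1, and MIR398b without 28DAS replicate 1. In the fit of the 2 ages alone, MIR160b, MIR160d, MIR166a, MIR166c, MIR166m, MIR396a and MIR398b lost their calls, and MIR166m also lost its call by DESeq2.

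Across all genes, 3664 rose and 4320 fell from 14 to 28DAS, 7984 together (36.3% of those tested; edgeR). Zm00001d033446 had 0 counts at 14DAS and 17.1 ± 2.21 CPM at 28DAS, at least 142-fold higher against a floor of 3 counts over the group. Zm00001d033152 had 7.03 ± 1.41 CPM at 14DAS and 0 counts at 28DAS, at least 88.5-fold lower against the same kind of floor. With fewer counts behind the floor, the bound for Zm00001d033446 was 90.6 without 14DAS replicate 1 and 51.0 without replicate 2, and that for Zm00001d033152 was 42.1 without 28DAS replicate 1 and 46.4 without replicate 2. The total was 14144 without 14DAS replicate 2 (7198 higher and 6946 lower), 3416 without 28DAS replicate 1 (1761 and 1655) and 3562 without 28DAS replicate 2 (1806 and 1756), and 1171 in the fit of the 2 ages alone (668 and 503).

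MIR172e, of a family known for targeting AP2-like flowering repressors, fell under the count filter of the bulk test and was singled out after its values were seen. It had 0 counts in the 8 libraries of 14 to 22DAS and 0.892 ± 0.547 CPM at 28DAS, at least 35.5-fold higher against a floor of 3 counts over those 8 libraries. With no count filter, the change from 14 to 28DAS passed the test (edgeR adjusted p = 0.00684) and that from 26 to 28DAS did not (edgeR adjusted p = 0.121). Its call from 14 to 28DAS was lost without 28DAS replicate 2, where the bound was 20.1, and its adjusted p lay between 0.00733 and 0.0997 over the fits without a library. The MIR156 family, which targets SPL transcription factors, had 6 counts over the 12 libraries and was not tested.

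The replicates did not lie equally close. The log2 CPM of the 14DAS libraries correlated across genes with r = 0.942, against 0.981 to 0.993 at the other ages, and the SD of the log2 difference was 0.820 at 14DAS against 0.296 to 0.495 elsewhere. The fit shares its spread over the ages, which may understate that of 14DAS. The p-values of comparisons with 14DAS may therefore be too small. Along the change from 22 to 28DAS over all tested genes, 26DAS replicate 1 lay 74.1% of the way and replicate 2 lay 44.2%. Libraries of 14, 16 and 18DAS lay between -8.31% and 6.30%.

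**Figure D3:**
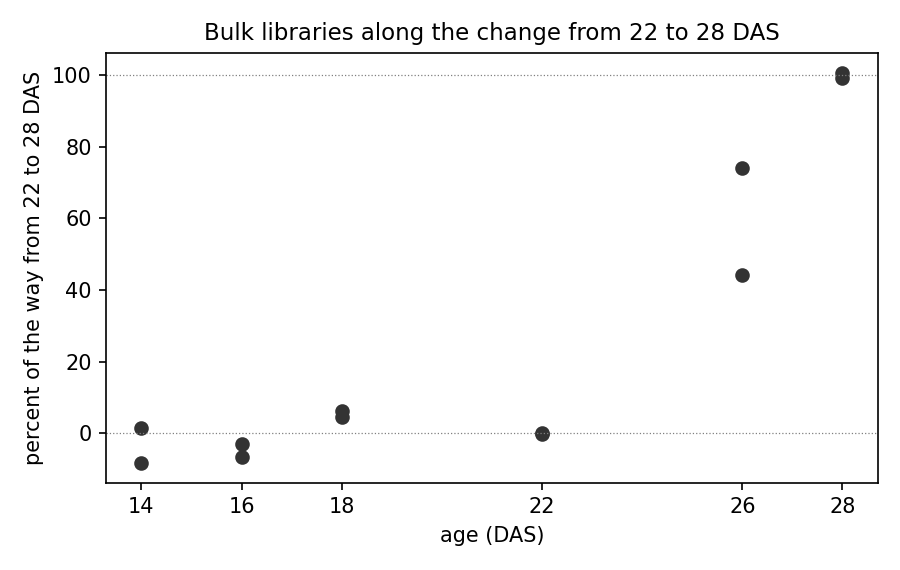
Position of each of the 12 bulk libraries along the change from 22DAS (0 percent) to 28DAS (100 percent), over all tested genes, by age (DAS). The 26DAS libraries lay at 74.1% and 44.2%.

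MIR398a, MIR398b and MIR408b are absent from the single-cell matrix. Each count per library of the 15 microRNA genes it holds was either 0 or at least 5. A filter per library may thus have removed low counts, so a 0 or an absence need not mean no transcripts. In the single-cell libraries, the copper-linked MIR528a had 0, 28 and 10 counts at 14, 22 and 26DAS. These were 0, 0.509 (95% exact Poisson interval 0.338 to 0.735) and 0.182 (0.0875 to 0.336) CPM, with no bound given for the 0. The bulk libraries of the same ages had 0.460 ± 0.295, 1.40 ± 0.273 and 0.231 ± 0.163 CPM. MIR159f had 0.536 CPM at 14DAS (0.340 to 0.804), 0.163 at 22DAS (0.0748 to 0.310) and 0.219 at 26DAS (0.113 to 0.382), where the bulk means of 22 and 26DAS were 9.04 and 1.62 CPM. MIR160d went from 1.82 CPM at 22DAS (1.48 to 2.21) to 0.712 at 26DAS (0.506 to 0.973), and its bulk means were 1.62 ± 0.729 and 4.25 ± 0.327 CPM. MIR169e, not tested in bulk, had 0.303 CPM at 14DAS (0.161 to 0.518) and 1.33 at 22DAS (1.04 to 1.67). With 1 library per age there is no replicate check and no test, and the intervals cover counting error only.

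Genes called in bulk were then compared with the summed single-cell counts of the same ages. The bulk libraries are of frozen SAMs and the single-cell libraries of protoplasts from apices with leaf primordia. Tissue, preparation and method therefore differ together. From 22 to 26DAS, 835 of 1328 genes moved the same way in both (62.9%, 95% exact binomial interval 60.2 to 65.5), against 54.0% of all 20936 genes tested in both. The share was 63.7% for the genes higher in bulk and 62.0% for those lower. Their median single-cell log2 changes were 0.150 and -0.106, against -0.0715 for all genes. That median under 0 favours agreement for the genes lower in bulk. From 14 to 22DAS, 171 of 355 genes moved the same way (48.2%, 42.9 to 53.5), against 47.7% of all genes. The share was 59.6% for the genes higher in bulk and 40.7% for those lower. Genes are not independent replicates, so these shares carry no p-value. Over all genes tested in both, the bulk and single-cell changes from 14 to 22DAS had a rank correlation of -0.0723. It was 0.101 without 14DAS replicate 1, -0.134 without 14DAS replicate 2, and -0.0952 and -0.0367 without 22DAS replicates 1 and 2. Its sign thus depends on which 14DAS library is used, and the share for 14 to 22DAS also moved with the library left out, as given below.

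Within clusters of at least 100 cells at both ages, the genes that rose in bulk from 22 to 26DAS had a median change above that of all genes in 15 of 15 clusters, and the genes that fell had one below it in 14 of 15. For 14 to 22DAS, the genes that rose in bulk lay above in 11 of 15 clusters (8 of 17 when clustered on 1000 variable genes) and the genes that fell lay below in 1 of 15 (0 of 17). For 22 to 26DAS, the differences from the median of all genes lay between 0.08 and 0.36 on the log2 scale for the genes higher at 26DAS and between -0.10 and 0.02 for those lower. All clusters of a comparison come from the same libraries, 1 per age, and use the same list of bulk genes. The counts of clusters are therefore not independent, and a difference between whole libraries would move them together.

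The 17563 cells fell into 20 clusters, named by number because the identifiers leading them carry no name here. Clusters 10, 11 and 14 were found again in 10 other clusterings, with at least 0.8 of their cells shared (intersection over union). Cluster 10, led by Zm00001d035689, held 1.31% of the 14DAS cells (95% exact binomial interval 1.03 to 1.63), 0.395% at 22DAS (0.25 to 0.591) and 0.969% at 26DAS (0.736 to 1.25). Cluster 11, led by Zm00001d027539, held 0.835% at 14DAS (0.617 to 1.11), 0.206% at 22DAS (0.106 to 0.359) and 0.735% at 26DAS (0.534 to 0.985). Cluster 14, led by Zm00001d033522, held 2.14% at 14DAS (1.78 to 2.55), 5.30% at 22DAS (4.74 to 5.91) and 2.86% at 26DAS (2.45 to 3.31). In total 8 clusters differed by a ratio of at least 2 between their highest and lowest age with intervals apart, and the other 5 (5, 7, 18, 19 and 20) fell under that overlap in at least 1 of the other clusterings. The depth of the libraries differed as given above, and the dissection and the protoplast yield could have differed too; each can set such shares.

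**Figure D4:**
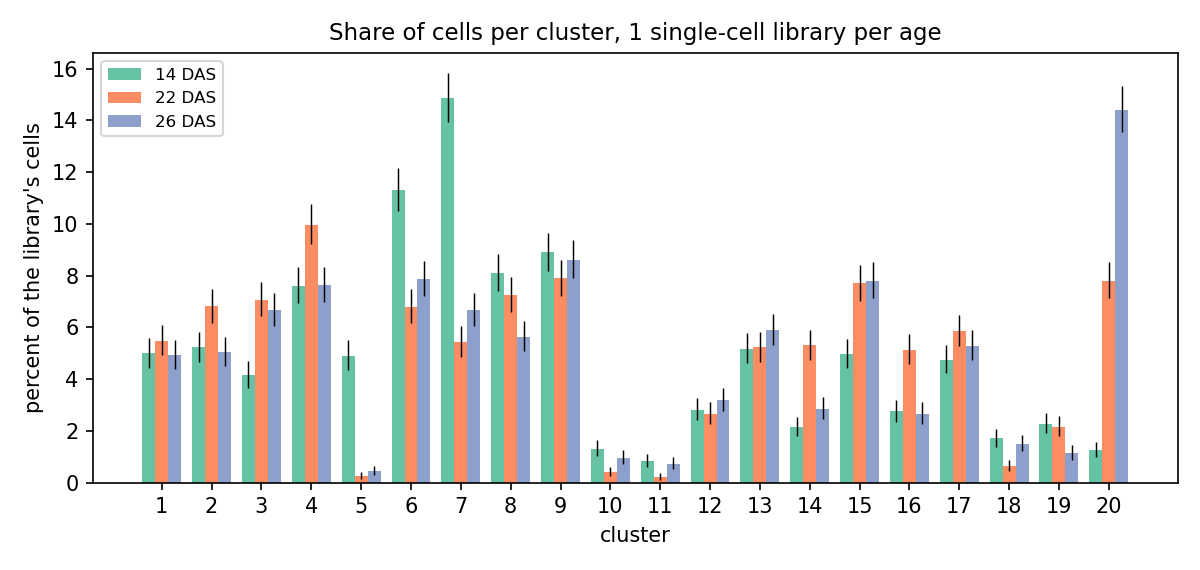
Percent of each single-cell library's cells in each of the 20 clusters, with bars for 14, 22 and 26DAS and 95% exact binomial intervals, which cover counting error only. Clusters 10 and 11 had their lowest share at 22DAS (0.395% and 0.206%) and cluster 14 its highest (5.30%); other clusters depend on the clustering.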

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

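The fits with 14DAS left out, the agreement of calls made without a library, the clustering without age-called genes, the other Leiden seeds, the coarser graph weights and the minimum of 50 cells were chosen after seeing the data. RLE size factors moved no count of bulk calls by over 1.5 times. With no count filter, the calls numbered 304 from 14 to 16DAS, 50 from 16 to 18DAS and 171 from 26 to 28DAS. With DESeq2 they numbered 1217 from 14 to 16DAS, 203 from 16 to 18DAS, 287 from 18 to 22DAS, 2218 from 22 to 26DAS, 590 from 26 to 28DAS and 1645 from 14 to 22DAS. With only the 2 ages compared, edgeR called 0 genes from 14 to 16DAS (1217 at an unadjusted p under 0.05) and 0 from 14 to 22DAS (1453). It called 1171 from 14 to 28DAS, 35 from 16 to 18DAS, 136 from 18 to 22DAS, 3391 from 22 to 26DAS and 965 from 26 to 28DAS. Those fits have fewer libraries to estimate the spread, yet the steps without 14DAS had more calls than in the fit of all 12 libraries. With 14DAS left out, the time course had 11892 calls, 16 to 18DAS had 261, 18 to 22DAS had 553, 22 to 26DAS had 4283 and 26 to 28DAS had 1233. The wide 14DAS pair (SD of the log2 difference 0.820, against 0.296 to 0.495 at other ages) feeds the spread shared by all ages. With it left out, each step between the other ages had more calls than in the fit of all 12 libraries. The few calls of some steps in that fit therefore do not show that little changed. The cause of the other moves was not tested.

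The replicate numbers were not taken to pair the libraries, since same-numbered libraries deviated together with a correlation over 0.1 in 5 of 15 pairs of ages (from -0.146 to 0.570). The 14, 18 and 22DAS libraries did so in each pair (0.570 for 14 with 18DAS, 0.207 for 14 with 22DAS and 0.158 for 18 with 22DAS). With the replicate number as a block, 5 genes were called from 16 to 18DAS, and no other count moved by over 1.5 times. The calls of MIR408b from 16 to 18DAS, of MIR398b and MIR408b from 18 to 22DAS and of MIR396a in the time course were lost with the block.

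Without each library in turn, where a lone library is assumed to vary like those of other ages, the time course had from 3053 calls (without 28DAS replicate 2) to 17160 (without 14DAS replicate 2). From 14 to 16DAS there were 16 (16DAS replicate 1) to 11709 (14DAS replicate 2), from 16 to 18DAS 0 (16DAS replicate 1; 794 at an unadjusted p under 0.05 by edgeR) to 263 (14DAS replicate 1), and from 18 to 22DAS 9 (22DAS replicate 1) to 554 (14DAS replicate 2). From 22 to 26DAS there were 239 (22DAS replicate 1) to 4294 (14DAS replicate 2), and from 26 to 28DAS 0 (8 of the libraries; 1233 to 2445 at an unadjusted p under 0.05 by edgeR) to 1228 (14DAS replicate 1). From 14 to 22DAS there were 33 (22DAS replicate 2) to 11093 (14DAS replicate 2), and from 14 to 28DAS 3416 (28DAS replicate 1) to 14144 (14DAS replicate 2). Agreement of the bulk and single-cell directions lay between 32.4% (22DAS replicate 1) and 53.9% (14DAS replicate 1) for 14 to 22DAS and between 64.0% (22DAS replicate 1) and 68.6% (22DAS replicate 2) for 22 to 26DAS.

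Of the 29 microRNA results between ages, 9 kept their call under every alternative: MIR159a, MIR159f, MIR167c, MIR394a and MIR408b from 14 to 28DAS, and MIR159f, MIR398a, MIR398b and MIR408b from 22 to 26DAS. Of their 500 alternative values, 419 stayed on their side of the threshold, 81 lost the call (64 of them without a library) and 0 changed sign. Of 438 values for 25 identifier results, 351 stayed, 87 lost the call and 0 changed sign. In the time course, 252 of 272 values for 16 microRNA genes stayed.

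The larger clusters depend on the clustering, which gave from 11 to 28 clusters. At resolution 0.5, 4 clusters had a share ratio of at least 2. In the reported clustering the ratios were 20.4 for cluster 5, 2.73 for cluster 7, 2.69 for cluster 18, 2.01 for cluster 19 and 11.5 for cluster 20. Each ratio below is that of the cluster sharing most cells, often few, so it is of partly other cells. At resolution 0.5 the ratios were 1.15 for clusters 5 and 7 and for cluster 20, 1.18 for cluster 18 and 1.08 for cluster 19. At resolution 1.5 they were 4.48 for cluster 18 and 8.69 for cluster 20. With 1000 variable genes they were 3.22 for clusters 5 and 7, 2.69 for cluster 20 and, in the other direction, 0.486 for cluster 19. Without age-called genes they were 4.96 for clusters 5 and 7, 1.19 for cluster 18, 4.57 for cluster 20 and, reversed, 0.513 for cluster 19. With Leiden seed 1 they were 11.97 for clusters 5 and 18, 5.77 for cluster 20 and, reversed, 0.0632 for cluster 7. Clusters 10, 11 and 14 kept their ratios in each of these. The gene list tests were not run, as the lists had 0 members, and the planned filter of 1000 counts per cell removes 0 cells. Depth limits the precision of transcripts with few counts, such as MIR528a (7 counts over both 26DAS bulk libraries) and MIR398a (3).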

Other observations

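The tests for the copper-linked microRNA genes, the depth test at 14DAS, and the swap and developmental tests at 26DAS were chosen after the results were seen. The mixture tests and the comparison of the 14DAS replicates with single cells were set before their first result, and were run again on the final clusters after earlier values were seen.

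MIR398a, MIR398b, MIR408b and MIR528a, from 3 families known for targeting copper proteins and grouped after their values were seen, had their highest mean at 18DAS and were called lower at 26DAS than at 22DAS (the call of MIR528a was lost in 7 of 12 fits without a library). For the highest mean of MIR398b and MIR408b, a single deviating library is argued against. Both kept their time-course call and highest mean at 18DAS in 12 of 12 fits without a library. Of these 12 fits, only those without an 18DAS library leave out part of the 18DAS mean, so the others bear little on it. Such a check was not made for the highest mean of MIR398a and MIR528a or for the age of the lowest mean. Scaling between libraries moves every gene alike, so it cannot set these 4 genes apart from the rest. Of all genes, 1.20% rose from 14 to 18DAS as far as the least of the 4 less 2 SE. From 18 to 26DAS, 1.37% fell so. These shares do not test scaling, because the genes and spans were picked for their change and TMM centres the changes. Handling of the bulk samples alone stays open. MIR528a, the only one of the 4 present in the single-cell matrix, had 0.509 CPM in the 22DAS single-cell library, above the interval of 26DAS. Its 0 at 14DAS may come from a filter, and each age has 1 such library. A hypothesis is that copper supply or demand at the apex differed with age or growth batch, which the design cannot separate; it was not tested, and copper measured in apices of each age from separate batches would test it.

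The 14DAS replicates differed most, and lower depth of replicate 1 is argued against by an SD of the log2 difference of 0.803 after thinning all libraries to 9153234 counts, against at most 0.499 at other ages. The change from 14 to 22DAS in single cells correlated across genes with the bulk change from replicate 2 (0.105) more than from replicate 1 (-0.132), a difference of 0.237. Whether replicate 1 departs from its age stays open: each age has 1 single-cell library, and the replicate difference at 18DAS ran along that at 14DAS (correlation across genes 0.570), so the difference is not one of 14DAS alone. Another mixture of cell types stays open, as the correlation of the replicate difference with a cluster's genes, at its largest in size, was -0.195 (-0.189 for the same cluster at 18DAS). Without replicate 1, 3854 of 11690 time-course genes were highest at 28DAS, 2437 at 16DAS and 1771 at 14DAS.

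The 26DAS replicates lay 74.1% and 44.2% of the way from 22 to 28DAS. A swap with 28DAS is argued against by the SD of the log2 difference of the 28DAS pair, 0.296, the lowest of the 6 ages. The replicate difference correlated across genes with the change from 22 to 28DAS (0.505 without the identifiers in an older format), so plants of replicate 1 may have been further along, but 1 pair cannot tell this from another cause along the same genes. A mixture of cell types also stays open (correlation largest in size with a cluster's genes -0.219).

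Of the identifiers that start with GRMZM5G, an older format, 64 were tested, and 46 were called lower at 28DAS than at 14DAS by edgeR. Their median log2 change was -2.99. Of all 22001 genes tested, 4320 were called lower, with a median log2 change of -0.024. What the GRMZM5G genes share beyond the format was not examined. The median log2 CPM of the 64 was 1.95 in 14DAS replicate 1, above that of each other library, against 0.82 in replicate 2. Without 14DAS replicate 1, 36 were called lower (median -2.41), and without replicate 2, 54 (-3.47); without 28DAS replicate 1, 12 were (-2.71), and without replicate 2, 28 (-3.53). At 26DAS, 62 of the 64 were lower in replicate 1 than in replicate 2.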
